A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

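Leaf RNA of the rice genotypes FR13A and IR24 was co-hybridised on 6 Agilent oligonucleotide arrays, with 2 arrays for untreated (constitutive) plants, 2 for plants submerged for 15 min and 2 for plants submerged for 24 h. Replicate 1 of each group had IR24 in Cy3 and FR13A in Cy5, and replicate 2 had the dyes exchanged, so a mean over both replicates of a group cancels a constant dye effect. Arrays were grouped as the sample labels state.

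Per the file headers, each array file holds mean spot and median local background values as scanner intensity in green and red, the processed intensity of both channels, and a log10 ratio of red over green. The submitters' processing notes name Agilent Feature Extraction 8.1, which per the file headers subtracted local background, detrended and dye-normalised each array. The deposited table of the whole series holds log10 ratios, and these correlated at 1 with the scanner ratio on replicate 1 arrays and at -1 on replicate 2 arrays, with every column median at 0, so its values are FR13A over IR24.

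Each array had 22575 spots, of which 162 negative and 918 positive control spots were left out, leaving 21495 gene probes. Background was corrected with normexp (offset 50) and each array was normalised by loess in limma 3.58.1 under R 4.3.3. Spots that the scanner software marked as non-uniform or as outliers were left missing. A probe was kept if it was well above background in at least 1 channel on at least 2 of the 6 arrays, which kept 20315 probes. Genotype differences were fitted on log2 ratios of FR13A over IR24 with 1 mean per time and a shared spread (3 residual degrees of freedom, 2.618 prior degrees of freedom). Changes within a genotype lie between arrays, so they were fitted with the separate-channel model of limma on the 12 channels after Aquantile normalisation, with an intraspot correlation of 0.494 and 3.491 prior degrees of freedom. That model used the 18907 probes with no missing channel and left out 1408 kept probes with a marked spot. It rests on normalisation between arrays and is secondary to the ratios. All tests were two-sided limma tests with Benjamini-Hochberg adjustment over all probes of a comparison, and a call is an adjusted p under 0.05.

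Gene names come from the description that the array files pair with each probe. Of the gene probes, 15930 had a named description (15227 of them kept) and 5565 were described as unknown. Many descriptions name the most similar sequence of another species, and such probes are written here as "like" that gene. The reference table of RefSeq genes matched 0 of the array accessions, so no coordinates are given. For each comparison the text takes its names from up to 10 probes higher and 10 lower with the largest log2 difference. These were described probes that were called and had the same direction on every array with a value, or no overlap between channel groups. Where fewer than 5 passed, the 10 described probes with the smallest p are listed as values. Up to 4 members per gene list with the smallest p, and 16 fixed genes, were added. Of the fixed genes, 7 had a probe whose description names them: ADH1, ADH2, PDC1, PDC2, ACO1, HB1 and AOX1A. No description matched SUB1B, SUB1C, RAMY3D, SLR1, SLRL1, ABA8OX1, ACS1, ACS5 or SUS1, so no probe was assigned to these genes. Probes described by a similar gene of another species could still measure some of them, which was not checked. ADH1 had 2 probes, and AK073964, with the higher mean intensity, speaks for it. Where no channel of the lower group was well above background, the fold was computed against the lowest well-above-background level of those channels and is written "at least".

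The comparisons, tests, naming rule, gene lists and most alternatives were fixed before the data were examined. The 24 gene lists were patterns on descriptions: fermentation, glycolysis and sucrose breakdown, amylases, ethylene, ERF and AP2 factors, gibberellin, abscisic acid, cell wall loosening, reactive oxygen, photosynthesis, chlorophyll breakdown, heat shock, hemoglobin, alternative oxidase, circadian clock, WRKY, cytochrome P450, glutathione transferase, disease resistance, transposon, ribosomal protein, histone and cell division, and, as markers of other tissues, seed storage and root or pollen. Lists with at least 5 measured members were tested with limma's cameraPR at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 210 tests. Hemoglobin, alternative oxidase and circadian clock had too few members and are given as counts. Under the preset correlation 13 tests passed, and 5 passed with the estimated one: heat shock in FR13A over IR24 at 15 min and in FR13A at 15 min, WRKY in IR24 at 15 min, and cytochrome P450 at 24 h in both genotypes. Median, mean and test of a list differed in sign in 50 of the 210 tests and in 0 of the 13 that passed.

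The arrays were scanned on 3 days, with 1, 2 and 3 arrays per day. Only 1 day holds a constitutive array together with a 15 min and a 24 h array, so each comparison between times has a value within 1 scan day, from 1 array per group and without a test. On that day FR13A is in Cy5 on the constitutive array and in Cy3 on the submerged ones, so a dye effect does not cancel in these values. Fits with scan day as a block, and channel fits that kept marked spots, were chosen after seeing the data. Other settings, chosen beforehand, covered background correction, normalisation, the deposited ratios, filters, array weights, a replicate term, a 2-fold minimum and leaving out each array. With an array left out or a day term added, the intraspot correlation could not be estimated reliably, so these channel fits used the value from all 6 arrays, as decided before their counts were seen. A group reduced to 1 array is assumed to vary like the others.

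The procedure was tested on simulated data with 18907 probes per comparison, of which 200 were changed. Of the probes changed 2-fold, the share recovered was 86% for FR13A over IR24 in constitutive plants, 93% at 15 min, 85% at 24 h and 99% across all times. It was 40% for the change of that ratio to 15 min and 67% for its change to 24 h. For the responses within a genotype it was 74% in IR24 and 71% in FR13A at 15 min, and 71% and 66% at 24 h. Each share rests on a single draw with 100 such probes, so differences between the shares may come from the draw. False calls ranged from 6 of 141 calls for the change of the ratio to 15 min to 18 of 187 for FR13A at 15 min. The simulated spread held no effect of scan day or dye. The p-values measure only the spread between samples, which can be technical. Figures were drawn with matplotlib 3.10.9.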

Results

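Leaf RNA of FR13A, a rice that tolerates submergence, and of IR24, a susceptible rice, was measured on 6 dual-colour arrays that each held both genotypes. The arrays formed 3 groups of 2: untreated plants sampled 14 days after sowing (constitutive), plants kept under water in clear bags for 15 min and sampled on day 14, and plants kept under water for 24 h and sampled on day 15. No group held plants handled without submergence, or unsubmerged plants of day 15. The share of gene probes well above background ranged over the arrays from 85.4% to 92.2% in Cy3 and from 81.8% to 95.3% in Cy5. Median signal was 3.34 to 5.67 times the median background in Cy3 and 3.05 to 11.4 times in Cy5. The number of arrays limits the precision. Values are log2 differences with the standard error (SE) of the limma fit, n = 2 arrays per time unless stated, and p-values are limma adjusted values. The probes come from cDNA sequences, and a sequence difference between the genotypes at a probe can also alter its ratio.

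**Figure D1:**
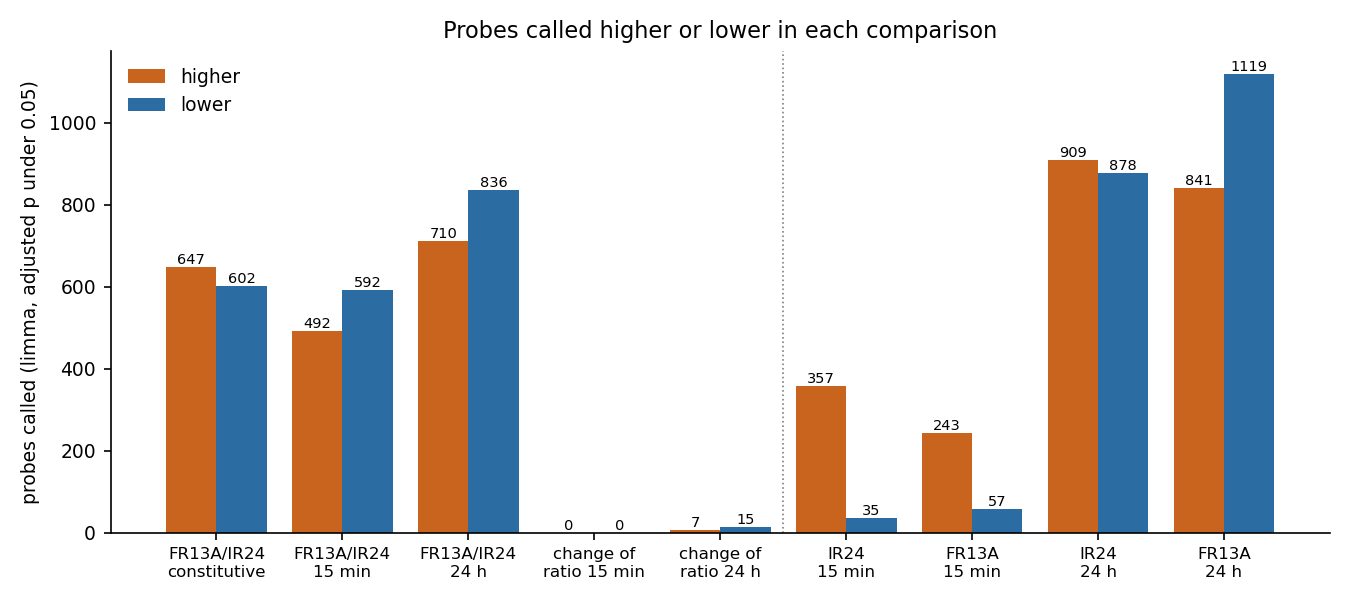
Number of probes called higher (orange) or lower (blue) by limma in each comparison, with ratio comparisons left of the dotted line and changes from constitutive plants within each genotype right of it. Calls numbered 0 for the change of the genotype ratio at 15 min and 22 at 24 h, against 1787 in IR24 and 1960 in FR13A after 24 h.

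The first question was which genes differed between the tolerant and the susceptible rice whatever the treatment. Across all 3 times (n = 6 arrays), a rice 1-aminocyclopropane-1-carboxylate (ACC) oxidase, the enzyme that makes ethylene (AK058296), was higher in FR13A by 4.08 (SE 0.09, adjusted p = 2.45e-05). An RD22-like dehydration-responsive gene (AK105947) was higher by 4.98 (SE 0.25, adjusted p = 0.000189), and a Rubisco small subunit gene of carbon fixation (AK068266) by 3.94 (SE 0.13, adjusted p = 0.000175). The SGR2-like probe AK100611 was higher by 4.22 (SE 0.13) and the ATP22a-like peroxidase AK064918 by 3.28 (SE 0.05). On the other side, the 21kd polypeptide gene AK105453 was at -4.30 (SE 0.12, adjusted p = 4.42e-05), a peptidylprolyl isomerase-like gene of protein folding (AK064825) at -3.63 (SE 0.09) and the MADS-box gene FDRMADS6 (AK061899) at -3.32 (SE 0.10). Each of these had the same direction on every array where it had a value. The Rubisco gene had a value on only 1 of the 2 arrays at 15 min. Among the fixed genes, pyruvate decarboxylase 2 (PDC2, AK101594), which takes pyruvate towards ethanol, was higher in FR13A by 0.90 (SE 0.06, adjusted p = 0.000574), PDC1 (AK100678) by 1.03 (SE 0.17, adjusted p = 0.0107; 2 of 6 IR24 channels well above background) and alternative oxidase AOX1A (AK064040) by 0.35 (SE 0.08, adjusted p = 0.0311). Another ACC oxidase, ACO1 (AK065039), was lower at -1.18 (SE 0.07, adjusted p = 0.000349). Alcohol dehydrogenase ADH1 was at -0.02 (AK073964, adjusted p = 0.94; its other probe AK069330 at 0.25, adjusted p = 0.0515), ADH2 (AK102799) at 0.19 (adjusted p = 0.148) and hemoglobin HB1 (AK064054) at 0.31 (adjusted p = 0.0612), and none of these passed.

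By gene list, across all times, the heat shock list had 14 higher and 3 lower of 72 measured (adjusted over the list alone, 17 and 3), among them the disaggregating chaperone HSP101 (AK105433) at 2.81 (SE 0.10), HSP26 (AK063618) at 0.99 (SE 0.05) and an HSC70-like gene (AK065431) at -1.33 (SE 0.08). The list as a set did not pass (adjusted p = 0.0598). Fermentation had 6 higher and 3 lower of 38 (list alone 8 and 4), with an alanine aminotransferase-like gene (AK067732) at -1.31, and glycolysis and sucrose breakdown 9 and 5 of 59 (14 and 6), with a cytosolic glyceraldehyde-3-phosphate dehydrogenase gene (AK099086) at 1.55. Ethylene had 5 and 3 of 26 (7 and 3), including the EIN2-like signalling gene AK105770 at -0.61, ERF and AP2 factors 2 and 5 of 22 (3 and 5; 1 of the called members is AK106354, 0.30, described by a human ERF-1 gene), and gibberellin 1 and 3 of 18 (2 and 4). Abscisic acid had 4 and 4 of 38 (4 and 4), where the called members include small GTPases of vesicle traffic such as rab5A (AK066784, 0.37) that the word pattern also caught. Reactive oxygen had 5 and 8 of 39 (7 and 10), photosynthesis 6 and 7 of 55 (6 and 7), cell wall loosening 5 and 1 of 46 (5 and 1), and chlorophyll breakdown 1 and 1 of 9 (1 and 1). Cytochrome P450 had 22 and 7 of 103 (23 and 8), glutathione transferase 9 and 4 of 51 (9 and 5), WRKY 3 and 1 of 26 (6 and 1) and amylases 1 and 0 of 17 (1 and 0). Alternative oxidase had 2 of 2 higher (2 alone), circadian clock 0 and 2 of 3 (0 and 3) and hemoglobin 0 and 0 of 2 (1 and 0). Ribosomal protein had 7 and 21 of 165 (7 and 21), and histone and cell division 2 and 3 of 45 (1 and 1). The markers of other tissues gave 1 and 0 of 11 for seed storage (0 and 0) and 7 and 4 of 30 for root or pollen (8 and 4), the latter including the root-specific genes RCc2 (AK062911, 0.88) and RCc3 (AK063684, -1.36). None of the lists large enough to test passed as a set in this comparison.

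In all, 4096 of 20288 probes were called across all times, 2056 higher and 2040 lower in FR13A. AOX1A lost its call without either constitutive array, 15 min replicate 2 or either 24 h array. Leaving out constitutive replicate 1 gave 2660 calls and leaving out 24 h replicate 2 gave 2627. The fit with scan day as a block called 4209, of which 3311 were shared. Global median centring in place of loess called 1037; the median size of the 4096 was 0.484 (median SE 0.157) there against 0.466 (0.0691), and 4095 kept their direction. Of the 80 called list members and fixed genes, 58 kept their call whichever array was left out.

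In untreated plants the same contrast asks what distinguished the genotypes before submergence. The RD22-like gene was higher in FR13A by 5.93 (SE 0.43, adjusted p = 0.00236), the Rubisco small subunit gene by 4.06 (SE 0.19), the rci-1 lipoxygenase gene (AK066737), whose enzyme oxidises fatty acids, by 4.05 (SE 0.28, adjusted p = 0.00216) and the ACC oxidase AK058296 by 3.85 (SE 0.15, adjusted p = 0.000609). The probenazole-inducible defence gene PBZ1 (AK071613) was higher by 3.46 (SE 0.57, adjusted p = 0.0269) and a terpene synthase-like gene (AK110925) by 3.17 (SE 0.29). The 21kd polypeptide gene was at -4.31 (SE 0.21) and a cellulase-like gene (AK064349) at -3.43 (SE 0.11). Both alternative oxidase genes were higher, AOX1b (AK107376) by 0.98 and AOX1A by 0.72 (adjusted p = 0.0417), as was PDC1, by 1.5 (SE 0.29, adjusted p = 0.0441; 1 of 2 IR24 channels well above background), whereas ACO1 was lower at -0.91 (SE 0.12, adjusted p = 0.0141). PDC2 (0.49, adjusted p = 0.0608), HB1 (0.69, adjusted p = 0.063), ADH1 (-0.19, adjusted p = 0.678) and ADH2 (0.02, adjusted p = 0.965) did not pass. The WRKY list of transcription factors had a median of 0.192 over 26 members and passed as a set (adjusted p = 0.029, but adjusted p = 0.585 with an estimated correlation), while 1 member, the WRKY4-like AK102093 at 1.66 (adjusted p = 0.00161), was called by itself (adjusted over the list alone, 1). Its median was 0.196 with scan day as a block and 0.222 within 1 scan day. Heat shock had 3 higher and 1 lower of 72 (list alone 3 and 1), with HSP101 at 2.59, root or pollen 2 and 1 of 30 (2 and 1), fermentation 2 and 1 of 38 (4 and 2), and ethylene 2 and 2 of 26 (4 and 3). Of 20314 probes, 1249 were called, 647 higher and 602 lower in FR13A. Leaving out constitutive replicate 1 left 178 calls and leaving out constitutive replicate 2 left 377, and of the 20 largest differences 5 and 4 then lost their call, PBZ1 and the terpene synthase-like gene in both cases. ACO1 and AOX1b also lost their calls without either constitutive array, and PDC1 and AOX1A without either constitutive or either 24 h array. Of the 48 called list members and fixed genes, 35 lost their call without constitutive replicate 1 and 28 without constitutive replicate 2, and 12 kept it whichever of the 6 arrays was left out. The fit with scan day as a block called 936 probes, 696 of them shared. Under global median centring 240 were called, and the median size of the 1249 was 0.941 (median SE 0.27) against 0.903 (0.118).

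After 15 min under water, many of the largest genotype differences involved the same genes: of the probes called here, 841 were also called in the same direction in untreated plants. The RD22-like gene was higher in FR13A by 5.41 (SE 0.43, adjusted p = 0.00375) and the ACC oxidase AK058296 by 4.37 (SE 0.15, adjusted p = 0.000637). HSP101 was higher by 3.06 (SE 0.17, adjusted p = 0.00122) and the Rubisco small subunit gene by 4.35 (SE 0.27, with a value on only 1 of the 2 arrays). The 21kd polypeptide gene was at -3.91 (SE 0.21) and the peptidylprolyl isomerase-like gene at -3.15 (SE 0.15). PDC2 was higher by 0.84 (SE 0.11, adjusted p = 0.0149) and ACO1 lower at -1.31 (SE 0.12, adjusted p = 0.0052), while PDC1 (1.15, adjusted p = 0.0962), AOX1A (0.44, adjusted p = 0.156), HB1 (0.28, adjusted p = 0.407), ADH1 (0.16, adjusted p = 0.764) and ADH2 (0.16, adjusted p = 0.636) did not pass. The heat shock list was higher in FR13A as a set, with a median of 0.0943 over 72 members (adjusted p = 0.0259, and 0.0416 with an estimated correlation). Of its members 6 were higher and 1 lower (adjusted over the list alone, 8 and 1), including an 18kDa heat shock protein-like gene (AK071240, 1.44, adjusted p = 0.0114) and HSP26 (1.07, adjusted p = 0.004). The median was 0.0535 with scan day as a block and 0.0629 within 1 scan day. Root or pollen markers had 1 higher and 1 lower of 30 (list alone 2 and 1), and seed storage 0 and 0 of 11 (0 and 0). Calls numbered 1084 of 20312 probes, 492 higher and 592 lower. They numbered 690 without constitutive replicate 1, 690 without constitutive replicate 2, 663 without 15 min replicate 1, 307 without 15 min replicate 2, 708 without 24 h replicate 1 and 708 without 24 h replicate 2. PDC2 and ACO1 lost their calls without 15 min replicate 2, and the 18kDa heat shock protein-like gene without 15 min replicate 1. Of the 45 called list members and fixed genes, 16 lost their call without 15 min replicate 1 and 22 without 15 min replicate 2. A scan day block called 340, 303 of them shared. Global median centring gave 183 calls, with a median size of the 1084 of 0.982 (median SE 0.267) against 0.928 (0.118).

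After 24 h under water the list of large differences had partly other names. The SGR2-like gene (4.63, SE 0.23, adjusted p = 0.000498) and the ACC oxidase AK058296 (4.0, SE 0.15, adjusted p = 0.000319) were again higher in FR13A. They were joined by a vacuolar proton-pumping pyrophosphatase gene (AK102146) at 3.81 (SE 0.43, adjusted p = 0.00673), pyruvate orthophosphate dikinase (PPDK, AK065739), which interconverts pyruvate and phosphoenolpyruvate, at 3.59 (SE 0.30, adjusted p = 0.00235), and a phosphoglycerate kinase-like gene of glycolysis (AK070705) at 3.39 (SE 0.10, adjusted p = 0.000244). The gene PibH8 (AK065693) was the furthest below IR24, at -5.08 (SE 0.21, adjusted p = 0.00034). PDC2 was higher in FR13A by 1.36 (SE 0.11, adjusted p = 0.00191) and ACO1 lower at -1.31 (SE 0.12, adjusted p = 0.00325). PDC1 was at least 1.34-fold higher, with 0 of 2 IR24 channels well above background, and did not pass (adjusted p = 0.454). AOX1A (-0.12, adjusted p = 0.729), HB1 (-0.05, adjusted p = 0.91), ADH1 (-0.02, adjusted p = 0.977) and ADH2 (0.38, adjusted p = 0.172) did not pass either. Glycolysis and sucrose breakdown had 6 higher and 2 lower of 59 (adjusted over the list alone, 7 and 3), including glyceraldehyde-3-phosphate dehydrogenase AK099086 at 2.12 and a sucrose synthase 3-like gene (AK099406) at -1.06. Fermentation had 2 and 1 of 38 (2 and 1), ERF and AP2 factors 0 and 3 of 22 (1 and 4), root or pollen 4 and 2 of 30 (4 and 3), with RCc2 AK062911 at 1.22 and RCc3 AK063684 at -1.14, gibberellin 0 and 2 of 18 (1 and 4), with the gibberellin-inactivating enzyme gene OsGA2ox3 (AK063973) at -0.82, and no list passed as a set. Calls numbered 1546 of 20292 probes, 710 higher and 836 lower, 784 without 24 h replicate 1 and 447 without 24 h replicate 2. The pyrophosphatase gene lost its call without either of these arrays, and the RD22-like gene (3.60) without the latter. Of the 52 called list members and fixed genes, 18 and 26 lost their call without these arrays. Blocking on scan day called 956, 783 of them shared. Centring each array by its median called 308, with a median size of the 1546 of 0.936 (median SE 0.271) against 0.911 (0.115).

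Across probes, the genotype ratio correlated between constitutive plants and 15 min at r = 0.881 (rho = 0.728), between constitutive plants and 24 h at r = 0.729 (rho = 0.556) and between 15 min and 24 h at r = 0.781 (rho = 0.672). Probes are not independent replicates, and no p is given. At 15 min and 24 h, arrays of the same replicate number shared a scan day as well as the dye orientation. These pairs of arrays correlated at r = 0.760 (replicate 1) and 0.681 (replicate 2). Constitutive arrays shared only the dye orientation with submerged arrays of their replicate number. For replicate 2 these pairs correlated at r = 0.840 with 15 min and 0.714 with 24 h, and for replicate 1 at 0.667 and 0.567. Replicates correlated with each other at r = 0.616 at 15 min and 0.723 at 24 h. In 680 probes the genotypes differed in the same direction at all 3 times.

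Whether submergence changed the genotype difference was tested on the ratios directly. From constitutive plants to 15 min, limma called 0 probes (smallest adjusted p = 0.598), with 427 at an unadjusted p under 0.05. The smallest p-values belonged to an F-box protein-like gene (AK068929, 1.09, SE 0.15), a cis-zeatin O-glucosyltransferase-like gene (AK101107, -1.19, SE 0.20), HSP26 (0.71, SE 0.12), a hexose transporter HT2-like gene (AK069202, -1.0, SE 0.17) and the lipoxygenase CM-LOX2 (AK066825, -0.77, SE 0.14). The fixed genes lay between -0.41 (ACO1) and 0.36 (ADH1, AK073964), with ADH2 at 0.14, PDC1 at -0.35, PDC2 at 0.34, HB1 at -0.40 and AOX1A at -0.28. The heat shock list moved up in FR13A relative to IR24 as a set, by a median of 0.0614 over 72 members (adjusted p = 0.034, but adjusted p = 0.0661 with an estimated correlation), with 0 members called (list alone 0) and a median of 0.0227 with scan day as a block and 0.0188 within 1 scan day. Scan day as a block, and leaving out any array, also gave 0 calls.

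From constitutive plants to 24 h, the ratio changed for 22 probes, 7 towards FR13A and 15 towards IR24. The phosphoglycerate kinase-like gene moved by 3.37 (SE 0.15, adjusted p = 0.0177): in FR13A it rose by 3.52 (SE 0.21), and in IR24 its value was 0.14 (SE 0.21, adjusted p = 0.791). The germin-like gene GER2 (AK059812) rose in both, by 4.14 in FR13A and 2.46 in IR24, a difference of 1.68 (SE 0.14, adjusted p = 0.0374). In the other direction, PibH8 changed by -3.55 (SE 0.29, adjusted p = 0.0374), a wall-associated kinase 2-like gene (AK111809) by -2.42 (SE 0.22, adjusted p = 0.0468), and an amino acid transporter-like gene (AK099094) by -1.93 (SE 0.13, adjusted p = 0.0269). An anthocyanidin reductase-like gene of flavonoid synthesis (AK072654) changed by -3.58 (SE 0.21, adjusted p = 0.0269), with a log2 change of -3.72 in FR13A and a value of -0.14 in IR24 (adjusted p = 0.796). A deoxyxylulose phosphate synthase-like gene at the start of plastid isoprenoid synthesis (AK100909) changed by -1.78, a glutathione transferase GST 20-like gene (AK064650) by -1.64 and the WRKY4-like gene by -1.61 (adjusted p = 0.0468). Among the fixed genes no change passed: AOX1A was at -0.84 (adjusted p = 0.339), PDC2 at 0.86 (adjusted p = 0.213), PDC1 at -1.04 (adjusted p = 0.697), HB1 at -0.74 (adjusted p = 0.49), ACO1 at -0.40 (adjusted p = 0.743), ADH1 at 0.18 (adjusted p = 0.969) and ADH2 at 0.35 (adjusted p = 0.81). By list, 1 of 59 glycolysis members moved up (list alone 2), and 1 of 26 WRKY members (list alone 1) and 1 of 51 glutathione transferase members (list alone 5) moved down. The count fell to 0 without constitutive replicate 1, constitutive replicate 2, 24 h replicate 1 or 24 h replicate 2, and to 7 without 15 min replicate 1 or 15 min replicate 2. With scan day as a block it was 0, and under global median centring in place of loess also 0, so all 22 calls end in either fit. The median size of these 22 was 1.83 (median SE 0.133), 1.92 (0.139) with scan day as a block, where the residual degrees of freedom dropped from 3 to 1, and 1.83 (0.372) under global median centring, where the SE grew. Of 469 probes whose ratio differed at least 2-fold between arrays scanned on different days, 76.3% went the same way within 1 scan day, where the dyes are exchanged between the times.

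**Figure D2:**
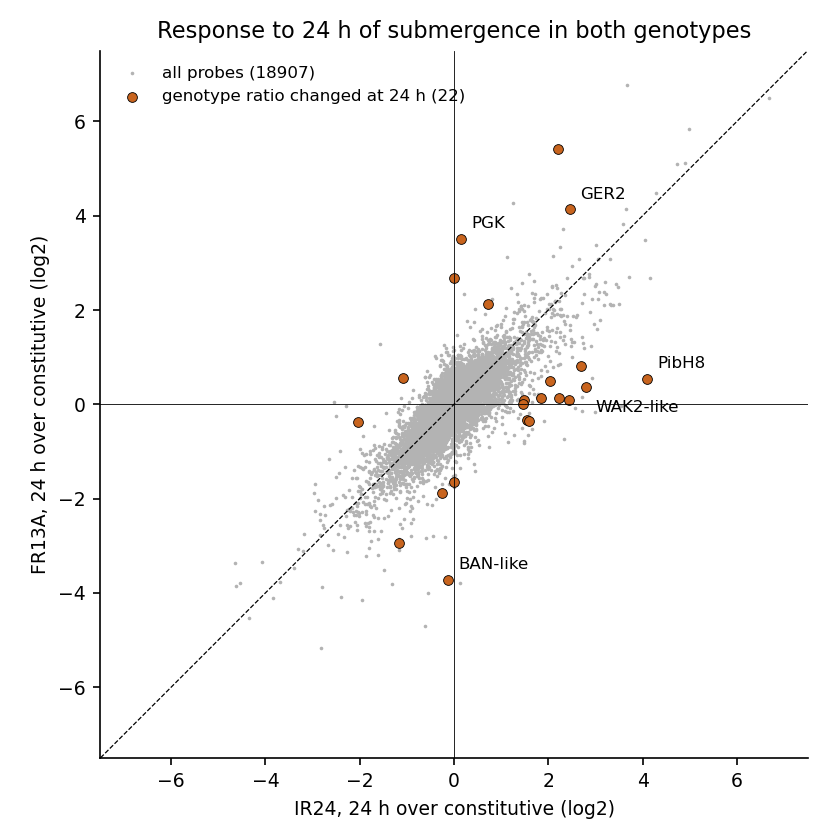
Log2 change from constitutive plants to 24 h of submergence in IR24 (horizontal) and FR13A (vertical) for 18907 probes (grey, n = 2 channels per group), with the 22 probes whose genotype ratio changed in orange and a dashed line of equal change. Phosphoglycerate kinase (PGK) lies at 0.14 in IR24 and 3.52 in FR13A, and the anthocyanidin reductase-like probe (BAN-like) at -0.14 and -3.72.

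Within each genotype, submerged plants were compared with constitutive plants from the channel intensities (n = 2 channels per group). In IR24 after 15 min, the genes with large rises included some for factors that bind the dehydration-responsive element: DREB1B (AK062422) rose by 5.49 (SE 0.60, adjusted p = 0.00163), DREB1A (AK105599) by 4.69 (SE 0.47, adjusted p = 0.00107) and a CBF1-like gene (AK106041) by 4.38 (SE 0.36, adjusted p = 0.000498). A cytochrome P450-like gene (AK067007) rose by 4.24 (SE 0.35), and a xyloglucan endotransglycosylase gene (AK070734), whose enzyme remodels cell walls, by 4.06 (SE 0.34, adjusted p = 0.000544). Some expansin genes, whose proteins loosen cell walls, were called lower: Os-EXP2 (AK070463) changed by -1.49 (SE 0.22, adjusted p = 0.00786), Os-EXP4 (AK058811) by -1.45 (SE 0.22) and EXPB11 (AK059638) by -1.23 (SE 0.19). An invertase gene (AK061240) rose by 1.82. Of the cell wall list 1 rose and 3 fell of 40 (adjusted over the list alone, 3 and 5), and it did not pass as a set. The heat shock list had 11 higher and 0 lower of 68 (list alone 13 and 1) and passed as a set (median 0.0127, adjusted p = 0.0157, but adjusted p = 0.0998 with an estimated correlation), led by the 18kDa heat shock protein-like gene at 3.48, the heat shock factor 7-like gene AK101700 at 3.44 and HSP101 at 2.56. WRKY factors had 4 higher and 0 lower of 24 (list alone 5 and 1) with a set median of 0.257 (adjusted p = 0.000477, and 0.0205 with an estimated correlation), among them the WRKY6-like AK105509 at 2.01 and the WRKY69-like AK060018 at 1.80. ERF and AP2 factors had 2 and 0 of 20 (5 and 0), with OsERF3 (AK111755) at 1.71. The word pattern of that list missed DREB1B, DREB1A and the CBF1-like gene, so its counts leave them out. Of the other-tissue markers, root or pollen had 1 and 0 of 28 (1 and 0), a pollen allergen-like gene (AK067214) at 2.85, and seed storage 0 and 0 of 11 (0 and 0). Medians with a scan day block were 0.025 for heat shock and 0.212 for WRKY, and within 1 scan day 0.0648 and 0.336. No fixed gene passed: ADH1 was at -0.16 (adjusted p = 0.912), ADH2 at -0.07, PDC1 at 0.39, PDC2 at 0.01, ACO1 at 0.40 HB1 at 0.01 and AOX1A at 0.47 (adjusted p = 0.432). In total 392 of 18907 probes were called, 357 higher and 35 lower. The count was 104 without constitutive replicate 1, 124 without constitutive replicate 2, 219 without 15 min replicate 1, 220 without 24 h replicate 1 and 219 without 24 h replicate 2. Of the 20 largest changes, 11, 10, 10, 2 and 2 lost their call in those fits, and 2 without 15 min replicate 2. DREB1B, DREB1A, the CBF1-like and the endotransglycosylase gene kept theirs in those fits. A scan day block called 55, 54 higher and 1 lower, all among the 392. In that fit 15 of the 20 largest changes lost their call, DREB1B included, as did 19 of the 26 called list members and fixed genes. The median size of the 392 was 1.29 (median SE 0.256, 4 residual degrees of freedom) there against 1.38 (0.211, 6). With 1 array left out, 10 of those 26 kept their call in every fit.

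In FR13A after 15 min, DREB1B rose by 4.62 (SE 0.60, adjusted p = 0.0063), the CBF1-like gene by 3.72 (SE 0.36, adjusted p = 0.00144) and the endotransglycosylase gene by 3.39 (SE 0.34). The 18kDa heat shock protein-like gene rose by 4.31 (SE 0.28, adjusted p = 0.000168), the heat shock factor 7-like gene AK101700 by 3.84 (SE 0.21, adjusted p = 4.5e-05), HSP101 by 3.03 (SE 0.23) and a low molecular weight heat shock protein gene (AK069547) by 2.62 (SE 0.24). Os-EXP2 changed by -1.58 (SE 0.22, adjusted p = 0.00679), Os-EXP4 by -1.33, EXPB11 by -1.22 and a histone H1-like gene (AK073668) by -1.78 (SE 0.21, adjusted p = 0.00418), whereas the beta-expansin EXPB4 (AK064012) rose by 1.17 and the invertase gene by 1.99. The heat shock list had 11 higher and 0 lower of 68 (adjusted over the list alone, 12 and 1) and a set median of 0.106 (adjusted p = 0.000477, and 0.0164 with an estimated correlation). WRKY had 2 higher and 0 lower of 24 (list alone 6 and 1) and a median of 0.165 (adjusted p = 0.0264, but adjusted p = 0.193 with an estimated correlation), and cell wall loosening 2 and 3 of 40 (3 and 7). Of the other-tissue markers, root or pollen had 1 and 0 of 28 (1 and 0), the pollen allergen-like gene AK067214 at 2.73, and seed storage 0 and 0 of 11 (0 and 0). The medians under a scan day block were 0.0464 for heat shock and 0.179 for WRKY, and within 1 scan day 0.0746 and 0.209. No fixed gene passed: ADH1 was at 0.20 (adjusted p = 0.803), ADH2 at 0.07, PDC1 at 0.04, PDC2 at 0.36, HB1 at -0.40, ACO1 at 0.00 and AOX1A at 0.19. In total 300 probes were called, 243 higher and 57 lower. The count was 74 without constitutive replicate 1, 27 without constitutive replicate 2, 161 without 24 h replicate 1 and 154 without 24 h replicate 2. Of the 20 largest changes 16 lost their call without constitutive replicate 2, DREB1B, the CBF1-like gene and the expansins included, and 8 without constitutive replicate 1, 4 and 5 without 15 min replicate 1 and 2, and 3 without either 24 h array. The heat shock genes named here kept theirs throughout. Blocking on scan day called 31, all higher and all among the 300, and 14 of the 20 largest changes and 14 of the 20 called list members and fixed genes lost their call. The median size of the 300 was 1.17 (median SE 0.246) there against 1.31 (0.201), and 5 of those 20 members kept their call whichever array was left out.

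In IR24 after 24 h, isocitrate lyase (AK063353), an enzyme of the glyoxylate cycle, rose by 6.67 (SE 0.52, adjusted p = 8.87e-05; 1 of 2 constitutive channels well above background), a receptor kinase-like gene (AK068816) by 4.90 (SE 0.18, adjusted p = 5.39e-06), an AP2/ERF gene like potato cip353 (AK106057) by 4.29 (SE 0.24) and PPDK by 3.67 (SE 0.38, adjusted p = 0.00041). A branched-chain amino acid transaminase-like gene (AK105963) rose by 4.16 (SE 0.34). The cold acclimation WCOR518-like probes AK062295 and AK062781 changed by -4.64 (SE 0.27) and -4.08 (SE 0.35), a lipoxygenase 2-like gene (AK071915) was at least 14.0-fold lower (adjusted p = 1.78e-05; 0 of 2 submerged channels well above background), and aspartate kinase-homoserine dehydrogenase, of amino acid synthesis (AK068391), changed by -3.40 (SE 0.27). Cytochrome P450 had 2 higher and 14 lower of 97 (adjusted over the list alone, 3 and 16) and was lower as a set (median -0.138, adjusted p = 0.0212, and 0.0416 with an estimated correlation), for example the avocado cyp71A1-like gene AK108512 at -1.79. Photosynthesis had 0 higher and 4 lower of 50 (list alone 0 and 4) and a median of -0.332 (adjusted p = 0.0456, but adjusted p = 0.664 with an estimated correlation), with the 17 kDa oxygen-evolving protein-like gene AK069170 at -1.64 and photosystem I subunit H (AK060254) at -0.95. WRKY had 6 higher and 0 lower of 24 (6 and 0; median 0.157, adjusted p = 0.034, but adjusted p = 0.216 with an estimated correlation). Ribosomal protein had 8 higher and 1 lower of 143 (4 and 1; median 0.144, adjusted p = 0.0157, but adjusted p = 0.897 with an estimated correlation). With days as a block the medians were -0.0969 for cytochrome P450, -0.41 for photosynthesis, 0.2 for WRKY and 0.0298 for ribosomal protein. Within 1 scan day, where the dyes are exchanged between the times, they were -0.114, -0.69, 0.251 and -0.0454, so the ribosomal median turned its sign. The medians within that day were taken over all kept members with a value there, not only those in the channel fit. Among the markers of other tissues, seed storage had 1 higher and 0 lower of 11 (2 and 1), a glutelin gene (AK107285) at 1.03. Root or pollen had 1 and 2 of 28 (2 and 2), with a SHORT-ROOT-like gene (AK070489) at -1.81. Probes described as RCc2 disagreed, with AK062911 at 0.80 and AK062848 at -0.79 (adjusted p = 0.0285).

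Other lists in IR24 at 24 h did not pass as sets. Ethylene had 7 higher and 2 lower of 26 (adjusted over the list alone, 7 and 2), with an ACC synthase ACS2-like gene (AK064250) at 1.98, an ACC oxidase-like gene (AK102472) at 1.34 and the ACC oxidase AK059964 at -1.18. Glycolysis and sucrose breakdown had 4 and 6 of 55 (5 and 7), with sucrose synthase 3-like AK099406 at 3.09. Fermentation had 2 and 2 of 32 (3 and 3), with lactate dehydrogenase (AK103257) at 1.61 and an aldehyde dehydrogenase ALDH3-like gene (AK104746) at 1.39. Reactive oxygen had 1 and 6 of 34 (2 and 8; adjusted p = 0.081), with an ascorbate peroxidase-like gene (AK069838) at -1.23 and catalase (AK066378) at -0.74. Gibberellin had 2 and 0 of 17 (3 and 0), with OsGA2ox3 at 1.88, and ERF and AP2 factors 4 and 1 of 20 (4 and 2). All 3 circadian clock members were called, the LHY-like probes AK111893 and AK111726 at -1.35 and -1.20 and the gigantea homologue AK072166 at 1.26 (adjusted over the list alone, 1 higher and 2 lower). No fixed gene passed: ADH1 was at -0.20, ADH2 at -0.24, PDC1 at least 1.32-fold lower (0 of 2 submerged channels well above background, adjusted p = 0.702), PDC2 at -0.44, ACO1 at -0.11, HB1 at -0.48 and AOX1A at -0.30. Probes called numbered 1787 of 18907, 909 higher and 878 lower. The count was 796 without constitutive replicate 1, 991 without constitutive replicate 2, 623 without 24 h replicate 1 and 741 without 24 h replicate 2, and 1 of the 20 largest changes lost its call, without 24 h replicate 1. Of the 66 called list members and fixed genes, 28, 25, 32 and 30 lost their call in those fits, and 27 kept it whichever of the 6 arrays was left out. A scan day block called 556, 549 of them shared, and 41 of those 66 lost their call, with a median size of the 1787 of 0.977 (median SE 0.234) against 1.01 (0.189).

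In FR13A after 24 h, PPDK rose by 6.77 (SE 0.38, adjusted p = 1.49e-05), isocitrate lyase by 6.50 (SE 0.52, adjusted p = 0.00011; 1 of 2 constitutive channels well above background), the receptor kinase-like gene by 5.12 (SE 0.18), the cip353-like gene by 4.48 (SE 0.24), the vacuolar pyrophosphatase by 4.27 (SE 0.49) and GER2 by 4.14 (SE 0.13, adjusted p = 1.41e-06). The RD22-like gene changed by -5.16 (SE 0.49, adjusted p = 0.000269), the rci-1 lipoxygenase was at least 25.9-fold lower (adjusted p = 4.53e-05; 0 of 2 submerged channels well above background), the terpene synthase-like gene changed by -3.99 (SE 0.35) and a drought-induced S-like ribonuclease gene (AK061438) by -3.88 (SE 0.25). Of the fixed genes, AOX1A fell, with a change of -1.14 (SE 0.20, adjusted p = 0.00578), as did AOX1b at -1.09 (SE 0.20), so that both alternative oxidase members fell (list alone 2). PDC1 (-1.47, adjusted p = 0.0805), HB1 (-1.22, adjusted p = 0.0662), PDC2 (0.43, adjusted p = 0.23), ACO1 (-0.51, adjusted p = 0.281), ADH1 (-0.02, adjusted p = 0.972) and ADH2 (0.11, adjusted p = 0.828) did not pass, while a hemoglobin Hb2-like gene (AK073898) fell, changing by -1.07 (1 of 2 members; list alone 2). Cytochrome P450 had 4 higher and 16 lower of 97 (adjusted over the list alone, 4 and 22) and was lower as a set (median -0.159, adjusted p = 0.00924, and 0.0164 with an estimated correlation), for example AK106424 at -3.82 and AK108512 at -2.50. Ribosomal protein had 6 and 1 of 143 (3 and 1; median 0.189, adjusted p = 0.0102, but adjusted p = 0.897 with an estimated correlation). Medians in the fit with scan day as a block were -0.155 and 0.125, and within 1 scan day -0.144 and 0.00186.

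Other lists in FR13A at 24 h did not pass as sets. Photosynthesis had 1 higher and 6 lower of 50 (list alone 1 and 6; adjusted p = 0.332), with AK069170 at -1.73 and photosystem I subunit H at -1.50. Markers of other tissues moved in this comparison too: seed storage had 1 and 0 of 11 (list alone 1 and 0), a glutelin gene (AK101299) at 1.11, and root or pollen 2 and 2 of 28 (2 and 3), with RCc3 (AK063684) at 1.29, RCc2 (AK062911) at 1.16 and the SHORT-ROOT-like gene AK070489 at -1.45. Reactive oxygen had 2 and 7 of 34 (3 and 8; adjusted p = 0.145), with AK069838 at -1.53. Ethylene had 5 and 2 of 26 (6 and 3), with AK102472 at 2.33, and WRKY 4 and 1 of 24 (5 and 1). Glycolysis and sucrose breakdown had 6 and 6 of 55 (6 and 8), fermentation 2 and 2 of 32 (2 and 2), heat shock 4 and 4 of 68 (5 and 5) and cell wall loosening 1 and 4 of 40 (1 and 5), with EXPB11 at -1.74. The LHY-like probes AK111893 and AK111726 were at -1.54 and -0.95 and the gigantea homologue AK072166 at 1.20 (list alone 1 higher and 2 lower of 3). In all 1960 of 18907 probes were called, 841 higher and 1119 lower. The count was 903 without constitutive replicate 1, 783 without constitutive replicate 2, 762 without 24 h replicate 1 and 987 without 24 h replicate 2. AOX1A lost its call without constitutive replicate 1 or 24 h replicate 1, and AOX1b without any one of these 4 arrays. Of the 69 called list members and fixed genes, 26, 28, 34 and 24 lost their call in those fits, and 30 kept it whichever of the 6 arrays was left out. Blocking on scan day called 562, 556 of them shared, and 37 of those 69 lost their call, with a median size of the 1960 of 0.952 (median SE 0.239) against 1.03 (0.192).

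The genotypes shared much of their response. At 15 min 205 probes were higher in both and 24 lower in both, and at 24 h 578 were higher in both and 661 lower in both. No probe was called in opposite directions. Across probes the responses of the genotypes correlated at r = 0.858 at 15 min and r = 0.816 at 24 h. FR13A and IR24 share arrays, which by itself gave a mean r of 0.495 and 0.489 in 20 simulated sets of unchanged plants. The simulation held no effect of scan day or array, which would enter both genotypes alike and could raise r and the shared calls. A call in 1 genotype and not in the other is not a tested difference, and the tests of the ratio above are those of the difference.

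**Figure D3:**
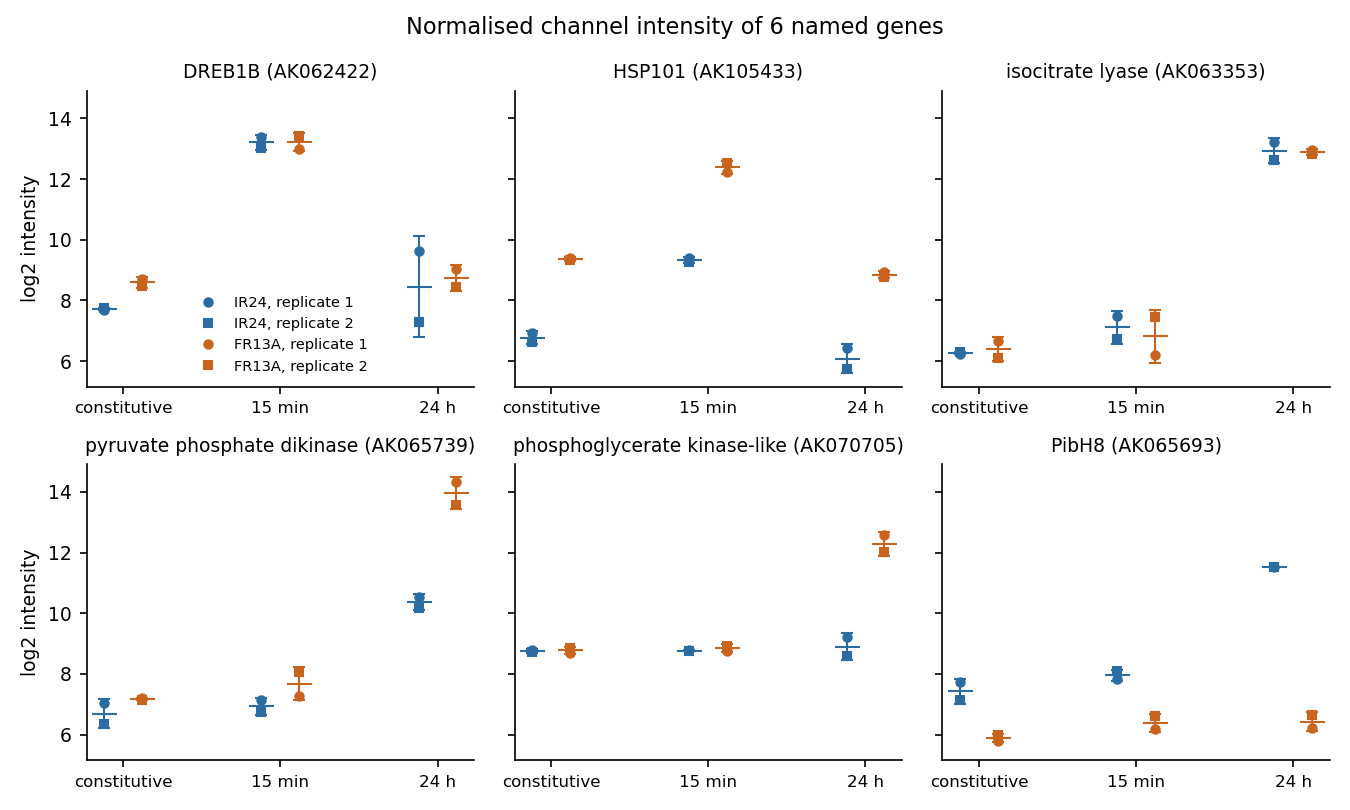
Normalised log2 channel intensity of 6 named genes in IR24 (blue) and FR13A (orange) in constitutive plants and after 15 min and 24 h of submergence, with circles for replicate 1, squares for replicate 2 and bars for the mean and SD (n = 2). DREB1B is high at 15 min in both genotypes, isocitrate lyase at 24 h in both, and phosphoglycerate kinase at 24 h in FR13A, where it rose by 3.52.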

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

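None of the tests here was chosen after its result was seen, except the fits with scan day as a block and the sizes given from them.

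The ratio of FR13A to IR24 changed from constitutive plants to 24 h for 22 probes, which stand out because the test of the difference between times passed for each over all 6 arrays. Under global median centring, and with scan day as a block, 0 probes passed with limma, with 337 and 3425 probes at an unadjusted p under 0.05. The changes were 3.37 (AK070705, phosphoglycerate kinase-like), 3.21 (AK107152), 2.68 (AK110639), 1.68 (AK059812, GER2), 1.66 (AK107013), 1.65 (AK103599) and 1.41 (AK066003). Towards IR24 they were -1.39 (AK067278), -1.45 (AK068675), -1.55 (AK071492), -1.61 (AK102093, WRKY4-like), -1.64 (AK064650, GST 20-like), -1.72 (AK110646), -1.78 (AK100909, deoxyxylulose phosphate synthase-like), -1.87 (AK065474), -1.88 (AK073328), -1.93 (AK099094, amino acid transporter-like), -2.11 (AK060656), -2.35 (AK067087), -2.42 (AK111809, wall-associated kinase 2-like), -3.55 (AK065693, PibH8) and -3.58 (AK072654, anthocyanidin reductase-like).

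Of the 22 probes, 86.4% were well above background in every channel of the 4 arrays compared. For these, signal near background is argued against as the cause of the change, and for the others it stays open. The share among all kept probes was not set beside this value. The 86.4% therefore does not show that the 22 were further above background than other probes. Scan day stays open. Of the 469 probes whose ratio differed at least 2-fold between constitutive and 24 h arrays scanned on different days, 76.3% went the same way between arrays scanned on 1 day, which lies between the bounds of 60 and 80% set beforehand. The dyes are exchanged in opposite ways in those pairs of arrays, so a dye effect lowers that share. With scan day as a block the median size of the 22 was 1.92 (median SE 0.139) against 1.83 (0.133), and the calls ended with 1 residual degree of freedom in place of 3; the 22 were chosen on the same arrays, so their size there does not settle scan day. A response to submergence that differs between the genotypes, and an effect of plant age that differs between them, cannot be told apart because no unsubmerged plants of day 15 were measured.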

How the results depend on the processing

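The scan day alternatives, and the channel fits that kept marked spots, were chosen after the results were seen. Among the settings listed here no named gene or list that passed under the main or the other setting changed sign. Of the 4096 probes called across all times, 4095 kept their direction under global median centring, and the lowest size was -0.109. Within 1 scan day the ribosomal protein median in IR24 at 24 h was -0.0454 against 0.144, over a partly different set of members. Under global median centring the calls were 240 in constitutive plants, 183 at 15 min, 308 at 24 h, 1037 across all times and 0 for the change to 24 h. With at least a 2-fold difference required they were 530, 481, 661 and 539 for the ratio at those times and across them, 915 in IR24 and 1019 in FR13A at 24 h, because fewer probes can pass. With only the arrays or channels compared, calls were 183 for the ratio at 15 min, 7 for its change to 24 h, 156 in IR24 and 144 in FR13A at 15 min, with fewer samples in the fit. Replicate 1 minus replicate 2 correlated across probes at r = 0.0996 between constitutive plants and 15 min. The value was 0.0596 between constitutive plants and 24 h, and 0.402 between 15 min and 24 h. Arrays of the same replicate number at 15 min and 24 h also shared a scan day. A replicate block gave 0 calls for the change to 24 h. It gave 165 in IR24 and 134 in FR13A at 15 min, and 1292 in FR13A at 24 h. With scan day as a block, which uses 2 more terms, the calls were 340 and 956 for the ratio at 15 min and 24 h, 0 for its change to 24 h, 55 and 31 at 15 min and 556 and 562 at 24 h in IR24 and FR13A. Of the list calls 5 passed with an estimated correlation. Leaving out 1 array gave 178 to 1303 calls for the ratio in constitutive plants, 307 to 708 at 15 min, 447 to 1479 at 24 h, 2627 to 3418 across all times, and 0 to 7 for the change to 24 h. It gave 104 to 404 in IR24 and 27 to 302 in FR13A at 15 min, and 623 to 1985 and 762 to 2196 at 24 h. Apart from the smaller fits named here, the cause of these moves was not tested. For single genes 9895 values kept their side of the threshold, 1550 lost their call and 24 gained one. For lists 619 kept their side and 11 lost their call. A value that passed in neither fit was counted as kept whatever its sign. Median signal over background, 3.05 to 11.4 times, limits what can be read from dim probes.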

Other observations

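The lists of amino acid and fatty acid breakdown and of jasmonate synthesis were chosen after the largest changes had been seen, and were tested without the members that prompted them; the fits with scan day as a block were also chosen afterwards.

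Some genes on the disease resistance and transposon lists differed between FR13A and IR24, in both directions. Across all times (n = 6 arrays) disease resistance had 14 higher and 17 lower of 141 measured (adjusted over the list alone, 14 and 17), including the NBS-LRR-like gene YR14 (AK065947) at -2.01 (SE 0.07) and a barley MLA13-like resistance gene (AK066312) at 1.51 (SE 0.05). Transposon genes had 7 higher and 7 lower of 59 (list alone 7 and 9), with a TdcA1-ORF2-like gene (AK066265) at 1.65, a Doppia transposase-like gene (AK063411) at -1.58 and an RF28-like retrotransposon gene (AK064547) at least 3.38-fold lower in FR13A. The word patterns also caught genes of other functions: among those called are a multidrug resistance protein-like gene (AK064221, -0.57), of a transporter family, and a ubiquitin and ribosomal polyprotein gene (AK059011, 0.29). Neither list passed as a set (adjusted p = 0.571 and 0.826). Cytochrome P450 had 22 higher and 7 lower of 103 and glutathione transferase 9 and 4 of 51, without passing as sets: the CYP71D10-like gene AK067543 was at -2.24 (SE 0.10), the cytochrome P450-like gene AK106424 at 2.13 (SE 0.14), and the glutathione transferases OsGSTU11 (AK061436) at -1.70 (SE 0.07) and OsGSTU17 (AK099489) at 1.31 (SE 0.09).

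After 24 h, some genes for breaking down branched-chain amino acids rose in both genotypes and others did not pass. An isovaleryl-CoA dehydrogenase-like gene (AK066314) rose by 2.59 in IR24 and 1.86 in FR13A (SE 0.38), a branched-chain keto acid decarboxylase-like gene (AK105761) by 1.54 and 1.43 (SE 0.19), and an electron transfer flavoprotein oxidoreductase-like gene (AK065934) by 1.58 and 1.68 (SE 0.26). A branched-chain keto acid acyltransferase-like gene (AK108134) was at -0.27 in IR24 and -0.21 in FR13A and a branched-chain keto acid dehydrogenase-like gene (AK110760) at -0.21 and -0.33, without passing. The 3-methylcrotonyl-CoA carboxylase gene AK061906 rose by 1.04 in FR13A and was at 0.60 in IR24 (adjusted p = 0.16). Of 18 measured members of the breakdown list 5 were higher and 0 lower in each genotype (adjusted over the list alone, 7 and 0). With limma 13 did not pass, and no member passed downwards.

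The hypothesis that transcripts of amino acid and fatty acid breakdown may be raised at 24 h was tested as a set with an estimated correlation. The list was higher in IR24 (median 0.507, adjusted p = 0.0293) and in FR13A (median 0.417, adjusted p = 0.0293). These p-values were adjusted only over the tests of the lists chosen afterwards. The genotypes share arrays, so these results are not independent, and the list was not tested with scan day as a block. Its word pattern also caught the asparagine synthetase genes AK101821 and AK100247, of amino acid synthesis, which passed in neither genotype. For jasmonate synthesis at 15 min, a list of 17 members gave an adjusted p of 0.067 in IR24 (1 higher, CM-LOX2 AK066825 at 0.68) and 0.216 in FR13A (0 higher), which leaves that hypothesis open.

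The 24 h response is argued against as wholly an effect of scan day: of 1477 probes that differed at least 2-fold across days, 93.6% went the same way within 1 day. With scan day as a block 556 probes were called in IR24 and 562 in FR13A, while the median size of the probes called without it was 0.977 against 1.01 and 0.952 against 1.03, with larger SE. Submergence and plant age or hour of harvest cannot be told apart, because 0 unsubmerged arrays of that age were measured.

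For the 15 min response, 95.9% of 586 such probes went the same way within 1 scan day, which argues against scan day as the whole cause. With scan day as a block 55 probes were called in IR24 and 31 in FR13A, while the median size of the probes called without it was 1.29 against 1.38 and 1.17 against 1.31, with larger SE and fewer residual degrees of freedom. Submergence and handling of the plants cannot be told apart, because 0 arrays of handled controls were measured.

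Chance is argued against, but not excluded, for the number of probes that differ between the genotypes across all times. Of the 32 sign patterns of the 6 arrays, only 1, the real one, gave as many calls (4096), and the highest other gave 397. Its share of 0.0312 is the smallest that 32 patterns can give. The pattern that follows the dyes gave 0 calls with limma. There a difference between the genotypes enters the spread, so this count cannot exclude a dye effect.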
